A study of Arabidopsis thaliana with 6 samples.

How the data were processed

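The deposited values are intensity values, 1 linear MAS5 signal per probe set of the Affymetrix ATH1 array, per the labels and the submitters' processing notes, which name MAS5 without a version. MAS5 combines the probe pairs of a probe set into 1 signal that is never negative and usually scales each array to a common target. The scaling target, background settings and genome build are not given in the sources used here, and detection calls were not used here. The trimmed means of the 6 arrays differed, so no common scaling target showed in the values. The exudate values were written with 1 decimal (100% of values on each exudate array) and the LMPC values with more digits, so the tables of both groups had been written out differently. The labels' protocols give poly-A RNA capture on oligo-dT beads, a linear amplification kit for exudate and the SMART kit with PCR pre-amplification for LMPC phloem. No batch other than the kit was given, and kit and group cannot be told apart.

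The table held 22810 probe sets, of which 64 were controls and were used only as controls. The probe table paired 13513 probe sets with 1 gene, 503 with several, which were not named, and 8730 were unnamed here. Of the single-gene probe sets, 13436 matched a gene of assembly TAIR10.1 by identifier and 77 did not, and 1580 had a symbol other than the locus code. Gene spans, introns included, were the gene lengths given for that assembly. Chloroplast genome transcripts were all probe sets of its plastid chromosome, and mitochondrial genome transcripts those whose symbol matched its mitochondrial genes, since the table did not carry the older locus codes of either. A gene was measured by the single-gene probe set with the highest mean over the 6 arrays, which gave 8638 tested genes.

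The following choices were made before the data were examined: the test, the filter, the pseudocount, 16 gene lists, the rule for named genes and most alternatives. The groups were exudate (n = 3) and LMPC phloem (n = 3), from the sample titles. The extract protocol given for the LMPC samples speaks of exudate as well, which conflicts with their titles and was not used to assign groups. A probe set was tested where its signal was above the array's 40th percentile on at least 3 of the 6 arrays. limma's lmFit and eBayes were run on log2(signal + 16) with no further normalization and no covariate, and a probe set was called at a Benjamini-Hochberg adjusted p under 0.05. That choice had assumed values scaled per array. Since none showed, the calls are given under other scalings as well. The log2 differences are exudate minus LMPC phloem. Limma's camera with a preset correlation of 0.01 compared each list of at least 3 tested genes with the other genes, with Benjamini-Hochberg adjustment over the 8 fixed lists that could be tested, and camera with an estimated correlation and fry stood beside it.

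The fixed lists were companion cell and sieve element, xylem and secondary wall, lignin synthesis, cambium and procambium, nuclear photosynthesis, epidermis and guard cell, glucosinolate and myrosinase, jasmonate and wound, early stress and cold, redox and metal-binding, cytosolic ribosomal protein, cell division, graft movement and reference genes, and the chloroplast and mitochondrial genome transcripts. Of 302 entries given by name, 45 had a probe set of their own in the table, 254 had none named here and for 3 the name and locus disagreed. The tests of these lists therefore rest on few genes. The table paired a smaller share of these entries than of all probe sets (13513 of 22810). The tested genes may therefore not stand for all genes of the array. A further 15 lists, adjusted as a family of their own, were chosen after seeing the data: all cytosolic ribosomal proteins, the mitochondrial respiratory chain, core histones and 12 families of gene symbols (among them UGT, SCPL, TBL, BGLU, SWEET, EXPA with XTH, GSTU, CYP, RALFL and IQD). The results of 2 of these families are not reported here.

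Named genes were chosen by a rule with 3 parts. The first part took SUC2, APL, AHA3, SEOR1, SEOR2, PP2-A1 and FT whatever their values. The second took, among called probe sets of 1 gene with a symbol, above the 60th percentile on every array of the higher group and without overlap between the groups, the 12 largest differences in each direction. The third took from each list the 2 called members with the smallest adjusted p in the more frequent direction and 1 in the other. List members outside the rule (RCA, GTR2, nad2, COR15A and the uncalled members) are named where a count was small, chosen after their values were seen. Brightness in a group meant a signal above the array's 75th percentile on all 3 of its arrays. The 3' to 5' ratios of control transcripts, and the spike-in means, were compared with exact two-sided permutation tests, for which 3 against 3 arrays give no p below 0.1.

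The fit was tested on simulated data with the LMPC means and the within-group spreads of the 15320 tested probe sets. Of these, 100 were given a log2 change of 1 and 100 a log2 change of 2. It recovered 4% of the former and 69% of the latter, and called 1 unchanged probe set. With so few changed probe sets the adjustment is stricter than in the real comparison, where 3853 were called. These shares therefore do not give the recovery of the real comparison. Alternatives were quantile normalization, median centring, centring on reference genes, pseudocounts of 1 and 64, no filter or a filter at the 60th percentile, a trended robust variance, a replicate block, leaving out each array, other limits of brightness, other list tests and the mean of a gene's probe sets. Scaling to the hybridization spike-ins, the poly-A spike-in ratios, the older control probe sets, leaving out arrays for the 3' to 5' ratios and the matching of genes by span were chosen after seeing the data. R 4.3.3 with limma 3.58.1 and Python 3.11.15 with pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.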

Results

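Poly-A RNA of the phloem of Arabidopsis thaliana was profiled on 6 Affymetrix ATH1 arrays, 3 of phloem exudate and 3 of phloem tissue. Phloem is the sugar-conducting tissue of the plant and holds sieve elements, companion cells and parenchyma. Exudate is the fluid that leaves severed sieve tubes, collected here in EDTA, a chelator that binds calcium and keeps the tubes from sealing. Whether it also held contents of other cut cells was not tested, and sap stands for this exudate below. The tissue was taken by laser microdissection and pressure catapulting (LMPC), in which a laser frees a small area of a section and lifts it into a collection tube. The plants had 8 h of light per day until they flowered. Exudate RNA was amplified with a linear kit of repeated in vitro transcription, and LMPC RNA with a kit that adds a PCR step, so the kit changed together with the sample type in every comparison of both groups. The mean signal of an array, with 2% of probe sets trimmed at each end, was 18.7, 17.8 and 28.0 on exudate arrays 1, 2 and 3, and 28.6, 26.5 and 22.7 on LMPC arrays 1, 2 and 3. The difference between the groups was -4.45 (exact permutation test, two-sided p = 0.3). Between 60.7% and 66.9% of the probe sets lay under a signal of 16 on an exudate array, and between 50.2% and 55.1% on an LMPC array. The labels do not say whether the replicates came from separate plants, so p-values measure only the spread between these samples, and the 3 arrays per group limit the precision.

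The first comparison asked which transcripts were more abundant in the sap and which in the tissue. PDF1.2 (AT5G44420), which encodes an antimicrobial plant defensin, had a signal of 519.5 ± 235 in exudate against 6.52 ± 7.18 in LMPC phloem (mean ± SD, n = 3 in each group here and below). COR47 (AT1G20440), a dehydrin gene induced by cold and drought, reached 1199 ± 251 in exudate against 103 ± 17.0. In the other direction, rps4 of the chloroplast genome, which encodes a protein of the small plastid ribosome subunit, had a signal of 17.4 ± 16.8 in exudate against 2330.4 ± 623 in LMPC phloem. BCAT4 (AT3G19710), an aminotransferase of methionine chain elongation in glucosinolate synthesis, had 116 ± 113 in exudate against 2316.5 ± 683. Their log2 differences, exudate minus LMPC phloem on the scale of log2(signal + 16), were +4.50 for PDF1.2 (limma, adjusted p = 6.71e-08), +3.35 for COR47 (2.45e-07), -6.22 for rps4 (1.25e-09) and -4.45 for BCAT4 (9.75e-07). This scale understates the change of genes whose mean is near or under 16 in either group.

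Of 15320 probe sets tested, limma called 3853 at an adjusted p under 0.05, 1303 higher and 2550 lower in exudate, and 3188 of the calls had at least a 2-fold difference, 1157 higher and 2031 lower. The share of calls that were higher in exudate was 33.8% for the values as deposited, 51.8% after quantile normalization (1997 higher, 1858 lower), 59.5% after median centring (2143 higher, 1458 lower) and 43.8% after centring on reference genes (1487 higher, 1911 lower). Scaling to the hybridization spike-ins, chosen after seeing the data, gave 88.6% (4570 higher, 588 lower). Median centring moved the median difference of all tested probe sets from -0.27 to 0.02. Relative to that shift, PDF1.2 stood at +4.79, COR47 at +3.64, rps4 at -5.93 and BCAT4 at -4.16. As deposited, after quantile normalization and after median centring alike, 2760 probe sets were called in 1 direction, 1303 higher and 1457 lower in exudate. The 3 arrays of one group all lay above the 3 of the other for 39.9% of the tested probe sets, against 10% by chance. Without exudate array 1 there were 2522 calls, 1521 of them lower, and without LMPC array 1 there were 1671 lower calls.

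**Figure D1:**
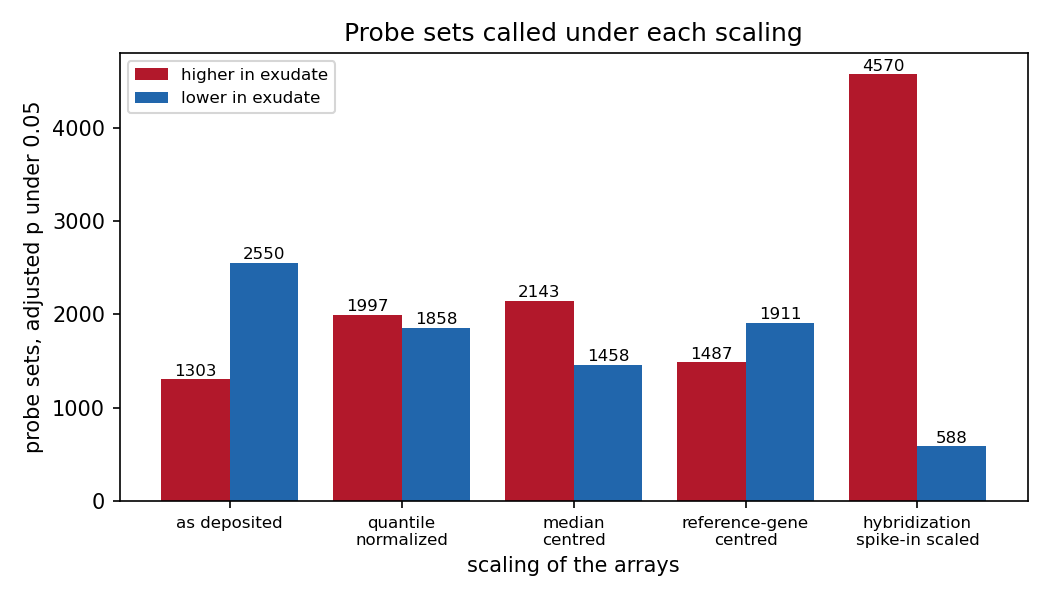
Bars give the number of probe sets called at an adjusted p under 0.05 as higher (red) or lower (blue) in exudate than in LMPC phloem under 5 scalings of the 6 arrays. Lower calls were more numerous as deposited (2550 against 1303) and after centring on reference genes, and higher calls were more numerous after quantile normalization, median centring and hybridization spike-in scaling (4570 against 588).

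Among named genes above the 60th percentile in the higher group, 98 were higher and 184 lower in exudate without overlap between the groups, and the 12 largest differences in each direction held under quantile normalization and median centring. Besides PDF1.2 and COR47, the genes higher in exudate included FDH (AT5G14780, formate dehydrogenase) with 1126 ± 446 against 54.9 ± 20.4, a log2 difference of +3.98. EXGT-A3 (AT2G01850), an endoxyloglucan transferase of the cell wall, was higher by +3.21, RALFL33 (AT4G15800), a RALF-like signalling peptide gene, by +2.82, and UGT72E1 (AT3G50740), a glycosyltransferase gene of phenylpropanoid metabolism, by +2.78. PDC2 (AT5G54960, pyruvate decarboxylase), DI21 (AT4G15910, a drought-induced gene) and cICDH (AT1G65930, the cytosolic isocitrate dehydrogenase) followed at +2.70, +2.66 and +2.50. ECS1 (AT1G31580, +4.02) and CP5 (AT1G64720, +3.74) were also among the 12. PDF1.2b (AT2G26020, +3.16) is a close paralog of PDF1.2, and its probe set is of the type whose probes can match several transcripts, so its value is uncertain. The adjusted p-values of these 12 genes lay between 6.71e-08 for PDF1.2 and 0.000314 for PDC2.

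The genes lower in exudate were led, after rps4, by SP1L5 (AT4G23496), a gene of the SPIRAL1-like family of microtubule proteins, with 10.8 ± 7.75 in exudate against 1341.5 ± 469 and a log2 difference of -5.64. GSTU20 (AT1G78370), a tau class glutathione transferase gene, had 9.57 ± 9.67 in exudate against 955 ± 425 (-5.21). UBC29 (AT2G16740), a ubiquitin-conjugating enzyme gene, differed by -5.06, MT1C (AT1G07610), a metallothionein gene, by -5.04, and MSRB5 (AT4G04830), a methionine sulfoxide reductase gene, by -4.95. The 12 genes of this direction were taken from those with a symbol, which 1580 of 13513 single-gene probe sets had. Chloroplast genes were listed by symbol, which can raise their share among the 12. Besides rps4, 5 of the 12 were chloroplast genome transcripts. These were ccsA of cytochrome c assembly (-4.72), psaI of photosystem I (-4.59), psbK of photosystem II (-4.25), rpl32 of the large plastid ribosome subunit (-4.21) and ndhD of the plastid NDH complex (-4.18). The LMPC signals of some varied widely between arrays, with 1096 ± 1070 for psbK and 597 ± 509 for ndhD. Within LMPC phloem, rps4 and these 5 were each highest on array 1. The adjusted p-values of these 12 genes lay between 1.25e-09 for rps4 and 2.16e-06 for psbK.

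**Figure D2:**
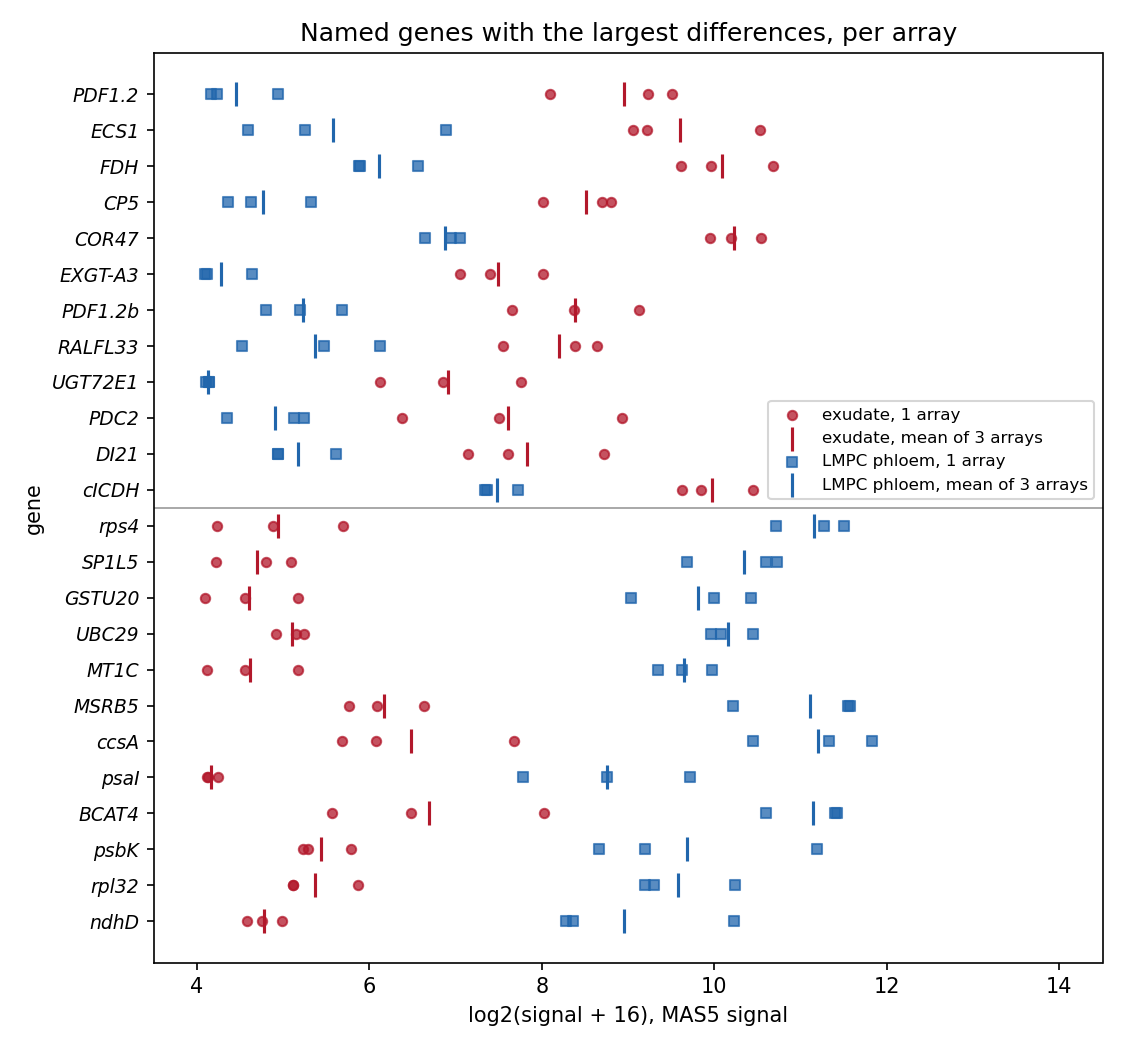
Each point is the log2(signal + 16) of 1 array for the 12 named genes with the largest differences in each direction, exudate as red circles and LMPC phloem as blue squares, with vertical bars at the group means of 3 arrays. The groups do not overlap for any of the 24 genes, as the choice of genes required, from PDF1.2 (+4.50) at the top to ndhD (-4.18) at the bottom.

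The second comparison asked how groups of genes with a shared role were placed between both kinds of sample. Chloroplast genome transcripts formed the group with the most calls. Of its 66 tested genes, 44 were lower and 1 was higher in exudate, and adjusted over the list alone 52 were lower and 2 higher. The mean log2 difference of the list was -1.80 (SD 1.45 over genes), against -0.29 for all 8638 genes, of which 6.23% were called higher and 17.5% lower. The shift from the other genes was -1.52 (limma camera, adjusted p = 1.36e-14), with an adjusted p = 0.398 when the correlation between genes was estimated. The exception was rbcL, the large subunit of Rubisco, with 176 ± 96.0 in exudate against 33.2 ± 24.3 and a difference of +1.96 (adjusted p = 0.00108). After median centring 40 chloroplast genes were lower and 2 higher, and after scaling to the hybridization spike-ins 29 were lower and 4 higher. Across these genes, which are not independent replicates, shorter gene spans (coding length with any introns) went with lower values in exudate (Spearman's rho = 0.336, n = 66). The means of the shortest 6 (-1.88) and of the others (-1.79) were close.

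Photosynthesis genes of the nucleus gave 3 higher and 0 lower of 7 tested genes, and adjusted over the list alone 3 higher and 1 lower. LHCB4.2 (AT3G08940), a chlorophyll-binding protein of the photosystem II antenna, had 518 ± 218 in exudate against 93.4 ± 63.1 (+2.37, adjusted p = 0.000373). LHCB4.1 (AT5G01530) was higher by +1.33 (adjusted p = 0.0275) and RCA (AT2G39730, Rubisco activase) by +1.01 (0.0482). The call of LHCB4.1 was lost without exudate array 2 (+1.38, adjusted p = 0.0587), exudate array 3 (+1.02, 0.107), LMPC array 2 (+1.21, 0.0934) or LMPC array 3 (+0.89, 0.162), with a pseudocount of 1 or of 64 and without the filter on dim probe sets. The list as a whole, with a mean of +0.38 (SD 1.31) and a shift of +0.68, did not pass (camera, adjusted p = 0.0927). Without LMPC array 1 its shift was +1.11 (adjusted p = 0.00473), and after scaling to the hybridization spike-ins it was +1.21 (0.00772). Mitochondrial genome transcripts, a further organelle group, had 2 higher and 2 lower of 10 tested, the same counts adjusted over the list alone, and this balance depended on the scaling, with 4 higher and 1 lower after median centring and 5 higher and 0 lower after scaling to the hybridization spike-ins. Their mean was +0.10 (SD 0.96), and the shift of +0.40 did not pass (adjusted p = 0.201). All 4 called genes encode subunits of respiratory complex I: nad1 (+1.63) and nad9 (adjusted p = 0.0295) were higher, nad4 (-1.39) and nad2 (-1.05) lower. The call of nad9 was lost without exudate array 1 or 3 or LMPC array 2 or 3 (adjusted p between 0.0894 and 0.133), with a pseudocount of 1 or of 64 and without the filter on dim probe sets, and that of nad4 after scaling to the hybridization spike-ins and with a pseudocount of 1. That of nad1 was lost with a pseudocount of 64 and without the filter on dim probe sets.

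Of 3 tested early stress and cold genes, 2 were higher and 0 lower in exudate, and all 3 were higher when adjusted over the list alone. The shift was +2.47 (camera, adjusted p = 2.26e-05), and it did not pass with an estimated correlation (adjusted p = 0.264). COR47 and STZ (AT1G27730, also known as ZAT10), a stress-induced zinc finger transcription repressor with 433 ± 114 against 76.3 ± 2.01 (+2.25, adjusted p = 2.77e-05), were called, and COR15A, a cold-regulated chloroplast protein gene, was not (+0.92, adjusted p = 0.0755). After quantile normalization, median centring, centring on reference genes and scaling to the hybridization spike-ins all 3 were called. Of the jasmonate and wound genes 2 were tested, PDF1.2, which was called, and ORA47 (+0.53, adjusted p = 0.239), with 1 higher adjusted over the list alone and both higher after scaling to the hybridization spike-ins.

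Cytosolic ribosomal protein genes had 2 higher and 0 lower of 5 tested, also when adjusted over the list alone. They were AT3G09630, with 221 ± 84.1 in exudate against 50.9 ± 9.17 (+1.78, adjusted p = 0.000559), and AT5G02870 (+1.24, adjusted p = 0.00632), both of the ribosomal protein L4 family. The call of AT5G02870 was lost with a pseudocount of 1. After median centring 3 were higher, and after scaling to the hybridization spike-ins all 5. The shift of +1.08 passed (camera, adjusted p = 0.00478), and it did not with an estimated correlation (adjusted p = 0.378). By fry, which tests the mean of a list and not its shift from other genes, the mean of +0.78 did not pass (adjusted p = 0.0942). Glucosinolate and myrosinase genes had 0 higher and 3 lower of 5 tested, also when adjusted over the list alone. Besides BCAT4 these were AT2G31790, a glycosyltransferase (-1.45, adjusted p = 0.00306), and GTR2 (AT5G62680), a glucosinolate transporter active in phloem loading (-1.46, 0.0042). After scaling to the hybridization spike-ins 1 gene of this list was higher and 1 lower. The shift of -1.17 missed the threshold (adjusted p = 0.0927). It passed after quantile normalization (-1.18, adjusted p = 0.0463), median centring (-1.17, 0.0486), centring on reference genes (-1.17, 0.00929), scaling to the hybridization spike-ins (-1.02, 0.0402) and without exudate array 3 (-1.33, 0.0269). It did not pass by camera with an estimated correlation (adjusted p = 0.378), and by fry the mean of -1.46 passed (0.0222).

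**Figure D3:**
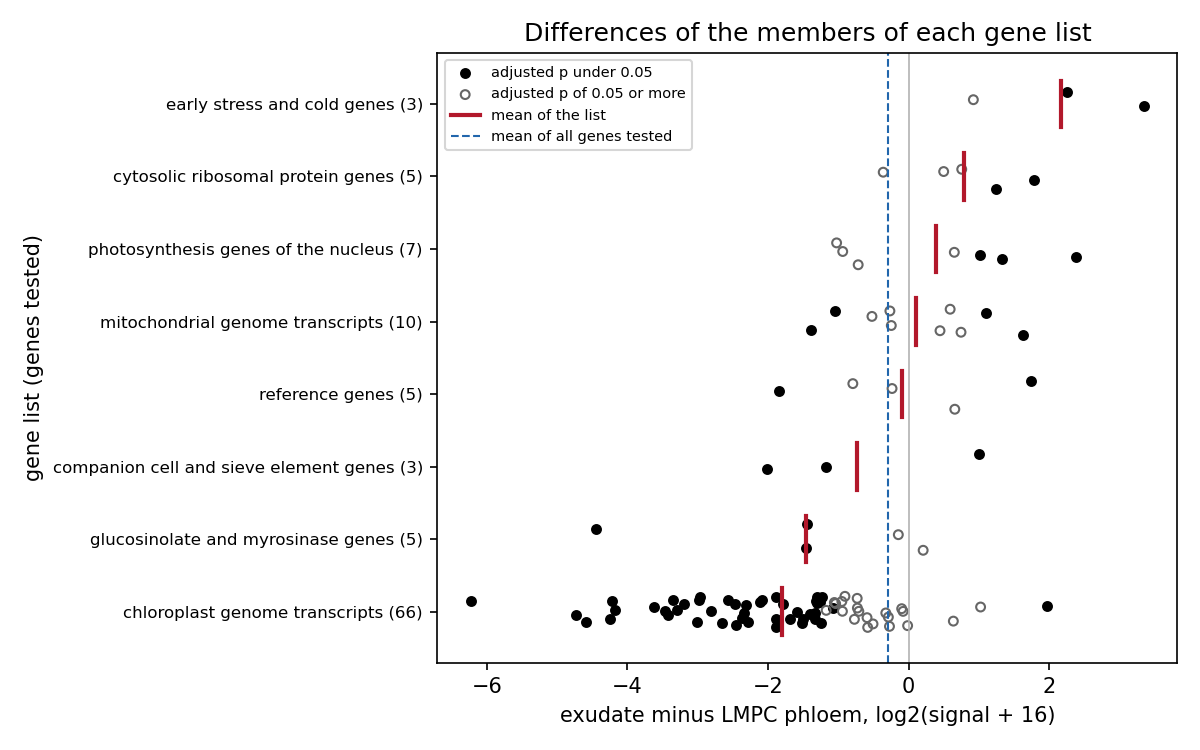
Each circle is the log2 difference, exudate minus LMPC phloem, of 1 gene of a list fixed in advance (filled, adjusted p under 0.05), red bars are list means, and the dashed line is the mean of all tested genes (-0.29). The chloroplast genome transcripts lie mostly below 0 (44 of 66 called lower). The sign of a mean depended on the scaling for the 3 tested genes of the companion cell and sieve element list (-0.73, and 0.28 after scaling to the hybridization spike-ins). It did so for reference genes as well (-0.10, and 0.20 after median centring).

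The companion cell and sieve element list, with 36 entries, was measured through 3 tested genes. These cannot stand for the cell types of its name, as most entries had no probe set of their own in the probe table used. CLE41 (AT3G24770), which encodes a peptide signal of the phloem that maintains the cambium, differed by -2.02 (adjusted p = 0.0006), and SWEET11 (AT3G48740), a sucrose exporter that feeds phloem loading, by -1.17 (0.014). CLE44 (AT4G13195), whose product is the same peptide as that of CLE41, was higher by +1.01 (0.0325). Adjusted over the list alone the counts were again 1 higher and 2 lower, and the shift of -0.43 did not pass (camera, adjusted p = 0.521). The mean of the list was -0.73 as deposited and turned to 0.28 after scaling to the hybridization spike-ins, where CLE41 and SWEET11 were not called and the counts were 1 higher and 0 lower. SWEET11 lost its call after median centring (-0.88, adjusted p = 0.0508) and without exudate array 1 (adjusted p = 0.0796) or LMPC array 1 (0.0683), and CLE44 without the filter on dim probe sets and without exudate array 1 or 3 or LMPC array 2 or 3 (adjusted p between 0.0975 and 0.113). Both lost their calls with a pseudocount of 1. SUC2, APL, AHA3, SEOR1, SEOR2, PP2-A1 and FT, phloem genes chosen in advance, were not analysed here. The probe table used assigned no probe set to them alone and left 8730 probe sets of the array unnamed. Among reference genes, GAPC2 (AT1G13440, cytosolic glyceraldehyde-3-phosphate dehydrogenase) was higher by +1.74 (adjusted p = 0.00069) and PEX4 (AT5G25760, also known as UBC21) lower by -1.84 (0.00348). Of 5 tested, 1 was higher and 1 lower, and adjusted over the list alone 1 higher and 2 lower. PEX4 lost its call without the filter on dim probe sets and after scaling to the hybridization spike-ins, where 2 genes of the list were higher and 0 lower. Their shift of +0.20 did not pass (adjusted p = 0.501) and differed in sign from their mean (-0.10) and median (-0.24), and the mean turned to 0.20 after median centring.

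The remaining lists held 1 or 2 tested genes each and had no list test. MT1C was the tested gene of the redox and metal-binding list. GUT2 (AT1G27440, also known as IRX10), a xylan synthesis gene of the xylem list, was lower by -1.09 (adjusted p = 0.0156), and its call was lost after median centring (-0.80, 0.0642), after scaling to the hybridization spike-ins (-0.10), with a pseudocount of 1 and without exudate array 2 (-0.88, 0.076) or LMPC array 1 (-1.05, 0.0501). AT1G22690 of the epidermis list was higher by +1.40 (adjusted p = 0.00789), and not without LMPC array 2 (+1.15, 0.0511). Adjusted over the list alone, each of these genes passed. FMA of the epidermis list (-0.59), HCT of lignin synthesis (-0.53), LHW of the cambium list (-0.74) and AUR1 of cell division (+0.44) were not called by either adjustment, and after scaling to the hybridization spike-ins HCT turned to 0.58 and LHW to 0.08, and AUR1 (1.16) was called higher. IAA18 of the graft movement list (-0.86, adjusted p = 0.0877) passed only when adjusted over the list alone, where it was the 1 gene tested, and it turned to 0.08 after scaling to the hybridization spike-ins.

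The third comparison asked which transcripts were abundant in both sap and tissue. Photosynthesis genes of the nucleus and cytosolic ribosomal protein genes were bright in both, with 7 of 7 and 5 of 5 genes above the 75th percentile on all 3 arrays of each group. Of 69 chloroplast genome transcripts, 13 were bright in exudate and 40 in LMPC phloem, with 10 bright in both. Among all 22746 probe sets, 3731 were bright in exudate, 3577 in LMPC phloem and 2044 in both, where independent sets of these sizes would share 587. Brightness ranks different probe sets on an array, and probe sets bright in most samples raise any such overlap. The value of 587 is therefore no test of sharing between sap and tissue. Over the tested probe sets, Pearson's r lay between 0.859 and 0.878 among exudate arrays, between 0.841 and 0.847 among LMPC arrays and between 0.499 and 0.535 across the groups, as a description across probe sets, which are not independent.

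The control transcripts moved with the sample type as well. The hybridization spike-ins, bacterial and phage cRNA added at hybridization, had a mean log2 signal of 9.19 ± 0.45 on exudate arrays and 10.58 ± 0.29 on LMPC arrays, a difference of -1.38. The poly-A spike-ins, bacterial RNA of known sequence that can be added to a sample before amplification, had 10.02 ± 0.67 and 8.61 ± 0.58, a difference of +1.41. For both, the exact permutation test gave p = 0.1 (two-sided), the smallest that 3 against 3 arrays allow. The log2 ratio of 3' to 5' signal of the GAPDH control was 1.22 ± 0.10 in exudate and 3.64 ± 1.57 in LMPC phloem (exact permutation test, p = 0.1). That of actin was 3.82 ± 0.57 and 4.50 ± 0.47 (p = 0.2, exact), and that of ubiquitin 2.54 ± 0.46 and 2.73 ± 0.35 (p = 0.7, exact). LMPC array 3 had a GAPDH ratio of 5.44, against 2.89 and 2.59 on LMPC arrays 1 and 2, and without it the GAPDH difference was -1.52 in place of -2.42. It was -1.30 for values with 16 added. Without exudate array 2 the actin difference was -0.35 in place of -0.68 and that of ubiquitin turned from -0.19 to +0.07, and without LMPC array 1 the actin difference was -0.41. Without LMPC array 2 the ubiquitin difference was close to 0 (-0.00044). With the older probe sets of the same transcripts, the GAPDH difference was -1.43 and the actin difference turned to +2.40. That GAPDH difference was -0.77 without exudate array 1 and -2.03 without exudate array 3. Leaving out arrays and using the older probe sets were chosen after seeing the data for these ratios.

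**Figure D4:**
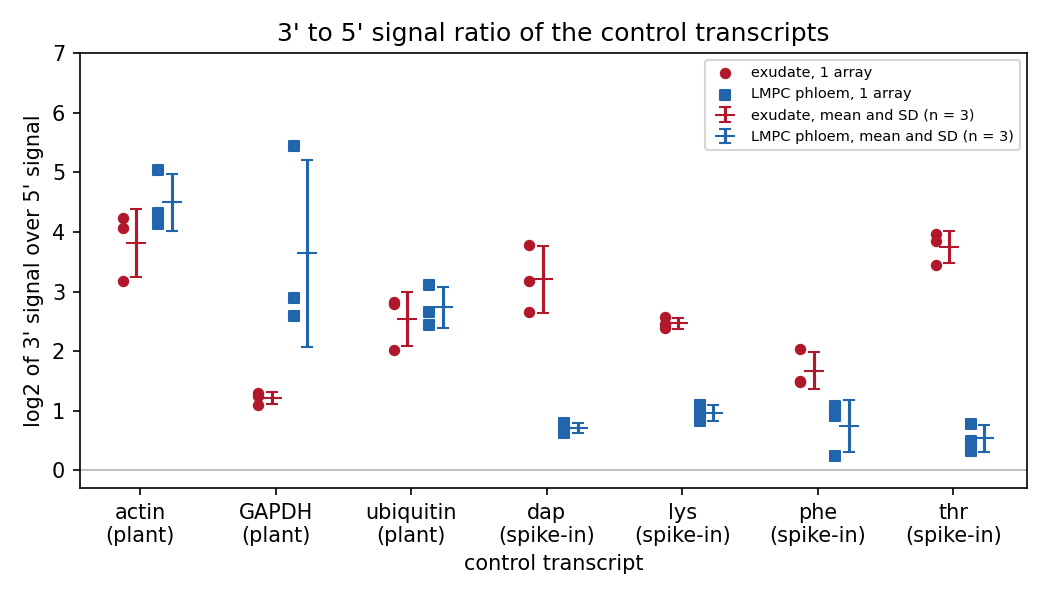
Points are the log2 ratio of 3' to 5' signal on each array for 3 plant control transcripts and 4 poly-A spike-in transcripts, with group mean and SD (n = 3 per group) beside them, exudate in red and LMPC phloem in blue. The spike-in ratios are higher in exudate, by +3.21 for thr and +0.93 for phe, while the plant ratio of GAPDH is lower (-2.42, and -1.52 without LMPC array 3, the highest GAPDH point), and the sign for actin (-0.68) turned with the older probe sets (+2.40).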

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

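Scaling to the hybridization spike-ins, the older control probe sets and leaving out arrays for the 3' to 5' ratios were chosen after seeing the data, and the other alternatives had been planned. The 3853 calls ranged from 2522 (without exudate array 1) to 3376 when an array was left out, and the lower calls from 1521 to 2469. Higher calls numbered 1997 after quantile normalization, 2143 after median centring and 4570 after spike-in scaling, and lower calls 1458 and 588 under the last 2. Median centring adds the same shift to every difference. Spike-in scaling raises exudate signals against LMPC signals by construction, since the spike-in means differed by -1.38 log2 between the groups. The turn towards higher calls under it follows from this. Why the spike-in means differed was not tested. Calls of at least 2-fold dropped to 947 with a pseudocount of 64, which shrinks differences by construction. The replicate numbers showed no pairing of the arrays (correlations of deviations -0.0044, -0.0162 and -0.074 for numbers 1, 2 and 3, with no sample closest to its own number). With 3 numbers this cannot exclude shared plants or days. A replicate block left 3427 calls, 1220 higher and 2207 lower.

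The nuclear photosynthesis shift ranged from 0.35 to 1.11 over the arrays left out, passing only without LMPC array 1 (adjusted p = 0.00473), and was 1.21 after spike-in scaling (0.00772). The glucosinolate shift ranged from -1.04 to -1.33 without single arrays and was -1.18, -1.17, -1.17 and -1.02 after quantile normalization, median centring, reference gene centring and spike-in scaling, with fry giving a mean of -1.46. The cause was not tested. With an estimated correlation, 0 of 8 fixed lists passed by camera (1 at an unadjusted p under 0.05, 3 by fry). This setting changes only the p, so the shifts of the lists that lost their pass (2.47 for early stress, 1.08 for ribosomal proteins and -1.52 for chloroplast transcripts) are the same by construction. After spike-in scaling 5 lists passed. By fry, the ribosomal protein mean of 0.78 did not pass (0.0942), and the SCPL family turned to -0.15 (0.0362), because fry tests the mean itself and not a shift from other genes.

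Mean correlations across the groups were 0.396, 0.578 and 0.616 with a pseudocount of 1, of 64 and without the filter, against 0.741 and 0.916 (pseudocounts) within exudate and 0.740, 0.901 and 0.860 within LMPC phloem. Bright probe sets in both groups numbered 4702 at the 50th percentile, 800 at the 90th and 3212 on 2 of 3 arrays. With the older control probe sets the group difference of the 3' to 5' ratio was 2.40 for actin, which reversed it, 1.91 for lys and 1.60 for phe; the cause was not tested. Without single arrays that of ubiquitin ranged from -0.339 to 0.0722, reversed without exudate array 2, and that of GAPDH from -2.95 to -1.52. Of 437 values of 23 gene lists 412 kept their side of the threshold, 7 lost and 17 gained the call and 1 reversed. A change of sign counted as a reversal only where a value passed, so the 412 include changes of sign. The respiratory chain shift was -0.26 as deposited and 0.20 after spike-in scaling, for example, and passed in neither. For fry the mean of a list stood in place of its shift. Of 1183 values of 74 named genes 1086 kept direction and call, 97 lost the call and 0 reversed. Signals under 16 on 50.2% to 66.9% of the probe sets of an array limit what can be said of dim genes.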

Other observations

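The 15 added gene lists, the counts over other splits for these and for single lists, and the tests of gene span, matched genes, organelle groups and 3' to 5' ratios given here were chosen only after the result was seen, and the other counts over splits of the arrays had been planned. Among all cytosolic ribosomal protein genes, AT4G34670, with a signal of 559 ± 184 in exudate against 89.0 ± 10.6 (mean ± SD, n = 3 each), differed by +2.41 on the log2 scale, and AT2G37190, with 481 ± 127 against 82.7 ± 6.82, by +2.30. AT3G28500, with 12.6 ± 11.3 against 145 ± 26.7, differed by -2.56. Of 116 tested, 23 were higher and 14 lower in exudate, a shift of +0.44 from other genes (limma camera, adjusted p = 0.000668), which did not pass with an estimated correlation (adjusted p = 0.675) and which passed by camera under 6 of 9 other splits of the arrays as well. After median centring 37 were higher and 9 lower, and after scaling to the hybridization spike-ins 79 were higher and 3 lower (shift +0.89). Of 123 with a probe set, 100 were bright in both kinds of sample. Mitochondrial respiratory chain genes of the nucleus gave 5 higher and 14 lower of 41 (adjusted p = 0.341). AT1G14450 differed by -3.48, with 115 ± 62.1 in exudate against 1333 ± 161, and MPPBETA (AT3G02090), the beta subunit of the mitochondrial processing peptidase, by +1.75. After scaling to the hybridization spike-ins the mean of this list turned from -0.56 to 0.64, with 15 higher and 1 lower.

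Families of gene symbols held single genes with large differences, while the shifts of the families given here did not pass by camera. By fry, which tests the mean of a list and not its shift from other genes, the lower means of TBL, SWEET, EXPA with XTH and BGLU (adjusted p = 0.0095 each), IQD (0.0118), GSTU (0.0207) and SCPL (0.0362) passed as deposited, where the mean of all tested genes was -0.29, and after scaling to the hybridization spike-ins these means lay above 0 except those of EXPA with XTH (-0.06) and GSTU (-0.11). TBL36 (AT3G54260), of a family of wall polysaccharide acetyltransferases, had 3.57 ± 2.79 in exudate against 267 ± 50.6 (-3.85). SWEET13 (AT5G50800), a sugar exporter gene, differed by -2.75, EXPA4 (AT2G39700), an expansin gene, by -1.95, and CYP78A9 (AT3G61880), a cytochrome P450 gene, by -2.37. The lists gave 1 higher and 3 lower of 17 for TBL (camera, adjusted p = 0.350), 0 and 3 of 11 for SWEET (0.341), 1 and 4 of 11 for EXPA with XTH (0.299) and 3 and 1 of 14 for CYP (0.216). UGT72E1 was among 3 higher and 2 lower of 25 UGT genes (0.123), with 5 and 0 after median centring and 9 and 0 after scaling to the hybridization spike-ins. RALFL33 and RALFL32 (AT4G14010, -2.08) differed in opposite directions among 1 higher and 2 lower of 6 RALFL genes (0.790). GSTU20 was the 1 called gene of 7 GSTU genes (0.578), and HTB4 (AT5G59910, a histone H2B gene, +1.43) of 6 core histone genes (0.341). For SCPL, 2 were higher and 4 lower of 18 (0.578), which turned to 3 and 2 after median centring and to 7 and 0 after scaling to the hybridization spike-ins. Counts were 0 and 2 of 12 for BGLU (0.466), which turned to 1 and 1 after median centring and to 3 and 1 after scaling to the hybridization spike-ins, and 0 and 1 of 9 for IQD (0.410), the last lost under each of the 4 other scalings. After scaling to the hybridization spike-ins the counts were 2 and 2 for TBL, 1 and 1 for SWEET and for EXPA with XTH, 2 and 1 for RALFL and for GSTU, 5 and 1 for CYP and 3 and 0 for core histones. The shifts of SCPL (+0.14) and RALFL (+0.02) differed in sign from their means (-0.15 and -0.27) and medians (-0.28 and -0.67). UGT had a mean of +0.14 and a median of -0.0041. After scaling to the hybridization spike-ins the means of BGLU (0.13), SWEET (0.02), TBL (0.11), IQD (0.04), SCPL (0.60) and RALFL (0.61) lay above 0 in place of below it, and those of SCPL (0.14) and RALFL (0.02) did so after median centring as well, and that of SCPL (0.07) after quantile normalization.

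The lower signal of chloroplast genome transcripts in exudate (mean -1.80, SD 1.45, 66 genes) was weighed against 3 technical sources. More green cells in the LMPC samples would lower the nuclear photosynthesis genes as much. Their mean was +0.38 (SD 1.31, 7 genes of 48 entries). A different capture of organelle transcripts would lower the mitochondrial genome transcripts, whose mean was +0.10 (SD 0.96, 10 genes). Both means lay above the chloroplast mean by more than 1 SD of their members. An SD over genes is not the uncertainty of a group difference, and these few genes were not matched for span to the chloroplast genes. Both values therefore do not decide whether either source was the whole cause. For 42 chloroplast genes with at least 10 nuclear genes of like span (within a factor of 1.5) and brightness (within 0.5 log2), the mean was -1.43, against -0.50 for the nuclear genes. This left -0.93 beyond the nuclear genes (below 0 for 35). Its SE of 0.206 counts genes as independent, while the estimated correlation over the 66 genes of the list was 0.67. That SE is therefore too small. The test does not decide whether a length effect shared with nuclear genes was the whole cause. The other 24, with spans up to 399 bases and a mean of -2.44, had no such match, so length may account for them as well. A difference between sap and tissue in plastid RNA stays open and untested, as the amplification kit changed with the sample type.

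Shorter nuclear genes lay lower in exudate, with Spearman's rho = 0.121 between gene span, introns included, and log2 difference across 8532 genes, and a mean of -0.60 (SD 1.11) for the shortest 853 against -0.25 (SD 0.82) for the others. Brightness of the probe sets was argued against as the sole source, since the lowest rho over 4 classes of brightness with equal numbers of genes and 9 pairs of an exudate and an LMPC array was 0.0414, still above 0. Across chloroplast genes rho was 0.336, with span as coding length with any introns. Their shortest 6 had a mean of -1.88 (SD 1.39), close to -1.79 (SD 1.47) for the others. Across 116 ribosomal protein genes rho was 0.394. These are a part of the nuclear genes and give no separate support. Those called higher had a median span of 1754 (n = 23) and those called lower 1322.5 (n = 14). Genes are not independent replicates in these correlations. A candidate explanation is that the PCR step of the LMPC kit favoured short cDNAs, which cannot be told apart from a difference between sap and tissue because each kit was used for 1 sample type.

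The 3' to 5' ratios of spike-ins and plant controls moved apart between the groups, by +2.04 for the spike-ins and -1.10 (SE 0.30) for the plant transcripts, means of 4 and 3 transcripts. Without LMPC array 3, which had the highest GAPDH ratio, the plant difference was -0.87. The difference between both was -3.13 (SE 0.42, and -2.87 without that array), and -2.14 (SE 0.52) with the older probe sets. These SEs are over arrays and not over transcripts. With the older probe sets actin moved by +2.40, like the spike-ins (+2.36), while GAPDH (-1.43) and ubiquitin (-0.32) did not. With these probe sets the spike-ins themselves differed in size, from +1.60 for phe to +3.14 for thr. The values of GAPDH and ubiquitin thus argue only against kits with an equal effect on all transcripts as the only source. A kit effect that varies with the transcript was not tested and stays possible. The comparison presumes that the spike-ins were added before amplification in both groups. For actin the question stays open. Shorter plant RNA in the LMPC samples before amplification may add to the difference. The plant difference was +0.21 (SE 0.43) with the older probe sets, and -0.22 with these when exudate array 3 was left out, so the tables leave this open. A difference in RNA length between sap and tissue stays untested as well.

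The 6 arrays have 10 splits into 3 and 3, too few for a share under 0.05. Each other split puts 2 arrays of one group with 1 of the other. It thus keeps a part of the real difference and adds the rest to the spread within its groups. Few calls are likely there for this reason alone, so the other splits do not show what would be found without any difference. The real split gave 3853 calls by limma against 0 as the highest of the others, where between 193 and 613 probe sets had an unadjusted p under 0.05, and 3188 against 0 calls of at least 2-fold, so 1 of 10 splits was as large in each. For fixed lists past the threshold by camera the real split gave 3 and the highest other 5, with 2 of 10 splits as large, and for added lists the real split gave 1 and the highest other 2, with 9 of 10 as large. Of the 9 other splits, 7 passed the chloroplast genome transcripts and 3 the early stress and cold genes. The cytosolic ribosomal protein genes passed under 3 and the nuclear photosynthesis genes under 4. Passing by camera at the preset correlation was therefore not confined to the real split. A real shift, kept in part by the other splits, could give this as well. The largest shifts in size under the other splits were 1.04 for the chloroplast transcripts (-1.52 under the real split), 1.08 for early stress (+2.47), 0.75 for the 5 cytosolic ribosomal protein genes (+1.08) and 0.37 for all cytosolic ribosomal protein genes (+0.44). For nuclear photosynthesis the largest other shift of 0.94 exceeded the real +0.68. The same held for the companion cell (0.47 against -0.43), mitochondrial genome (0.41 against +0.40) and reference lists (0.32 against +0.20). It held for the respiratory chain (0.39 against -0.26), core histones (0.51 against +0.42), SCPL (0.16 against +0.14) and RALFL (0.26 against +0.02) as well.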
